A study of Rattus norvegicus with 39 samples.

How the data were processed

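Gene expression in the periaqueductal gray was measured on 39 arrays, each with 2 colours, in 8 groups set by stimulation frequency, responder class and time. The groups follow the sample titles. The labels of the 100 Hz NR rats disagree in 1 field, whose abbreviation reads HR; the title, characteristics and description say NR, which was used. The series text names the dorsal horn once, while every sample label names the periaqueductal gray. The labels give each array of a group to a separate rat.

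Each array has a file per channel. The deposited intensity values are ImaGene spot intensities (version 5.1 per the file headers, while the labels name another version), neither background corrected nor normalized. Cy3 holds the stimulated rat and Cy5 the control pool, per the labels. The deposited series matrix holds log2 ratios for 11276 of the 12288 spots. Its processing steps are not given in the sources used here. Its log base and direction were set by comparison with the scanner files (correlation over spots 0.735 to 0.929 per array), and its column medians lay between -0.01 and 0.02; the exact scale and centring stay unknown. No per-sample column was left unused.

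Signal means and background medians were corrected in limma 3.58.1 (R 4.3.3) with normexp and an offset of 50, fitted on all spots, and log ratios were normalized within each array by loess. The 1012 spots outside the series matrix had weight 0 in the loess and were left out of the tests, as were spots marked bad by the scanner software (0 to 308 per array). A spot was tested when either channel exceeded its local background by 2 background SDs on at least 4 arrays of the time point. No spot was averaged, because every spot has its own identifier. Median signal over background was 3.36 to 10.7 in Cy3 and 6.79 to 14.1 in Cy5. Arrays correlated between -0.23 and 0.89 over spots, which are not independent replicates.

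Linear models with 1 coefficient per group were fitted with lmFit and eBayes, 1 per time point and 1 over all 39 arrays for the time comparison. Adjusted p-values are limma's moderated tests, two-sided, with Benjamini-Hochberg adjustment at 0.05. The fits were tested on simulated data with the spread of the real spots and 200 changed spots. The simulated noise was drawn independently for each spot and array, without slide run, block position or correlation between spots. For changes of 0.3, 0.5 and 1 between frequencies at 1 h, 49.3%, 76.1% and 97.0% were called, with 16 unchanged spots called. The control pool was simulated 20 times as the mean of 5 rats with the spread of the stimulated rats.

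The groups, the comparisons with their tests and most alternatives were set before the data were examined. The print-tip loess, the removal of spots marked empty, and the image folder as a block were chosen after seeing the data, as were the rules for naming spots. So were the tests of slide run, of printed DNA, of a frequency effect shared by both times, of HR minus NR correlations between conditions and of separate levels. The rule set before took genes by symbol. As 0 of the 12288 identifiers matched the gene table used here, it could not be applied, and the 32 gene lists and the genes fixed by name were not analysed here. In its place the 2 largest rises and 2 largest falls of the frequency comparison at 1 h are named. That rule was first applied to all called spots and then, after spots with Cy3 at background at 100 Hz were seen, limited to spots above background in both channels on every array at 1 h. The 1 spot of the responder comparisons is also named.

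Slide runs were formed from slide numbers that share all but their last digits, and image folders from the headers. Runs served as a fixed block at 1 h, where 3 of 4 held more than 1 group, and as a random block at 24 h, where 5 runs held 1 group each. Folders served as a fixed block at 24 h. Other alternatives were no background correction, plain subtraction, median centring, Aquantile, other dim filters, the series matrix values, array weights, 1 fit for all arrays, fits of only the groups compared, the replicate number as a block, and leaving out each array. For the comparisons between groups, 100 splits of the arrays were fitted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.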

Results

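The series measured RNA of the periaqueductal gray, a midbrain region of descending pain control, in Sprague-Dawley rats after electroacupuncture, in which current is passed through acupuncture needles. Rats received 30 minutes of stimulation at 2 Hz or 100 Hz, were tested for analgesia and were killed 1 h or 24 h later. The labels divide them by their analgesic response into high responders (HR) and low responders (NR). This gave 8 groups of 5 rats, except 4 rats in the 2 Hz NR group at 1 h, and 39 arrays of 12288 spots. On each array the RNA of 1 stimulated rat was labelled with Cy3 and a mixture of RNA from 5 unstimulated rats with Cy5. Values are log2 ratios of the stimulated rat over that control pool. Between 85.4% and 98.6% of the 11276 spots of the series matrix were above background in at least 1 channel on an array, and the number of arrays limits the precision. The files used here do not pair the spots with genes, so results are given as counts of spots and, for 5 spots, by grid position; what these spots measure is not analysed here.

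The first question, from the labels, was whether high and low responders differed. At 1 h after 2 Hz stimulation, 1 of 11207 spots differed between HR and NR rats. Spot Sr06Sc02R03C07 was lower in HR rats by a log2 difference of -0.55 (SE 0.08, limma adjusted p = 0.0266). Its mean log2 ratio was -0.19 ± 0.05 (SD, n = 5) in HR and 0.36 ± 0.23 (SD, n = 4) in NR rats, and all 5 HR values lay below all 4 NR values. At 100 Hz its difference was 0.08 (SE 0.08, adjusted p = 0.765), and the response by frequency interaction of this spot did not pass (0.63, SE 0.11, adjusted p = 0.123). The spot was chosen after its values were seen. When only the HR and NR rats of 2 Hz entered the fit, the difference stayed at -0.55 and the SE rose to 0.10 (limma adjusted p = 0.558). With slide run as a block it was -0.55 (SE 0.11, limma adjusted p = 0.641), so the call was lost in both. Counting these, the call was lost in 12 of 33 alternatives. Other settings raised the count of 1: it was 9 with plain background subtraction, 3 with median centring, 22 with a replicate block, 30 in a single fit of all 39 arrays and 616 with array weights. At 1 of 16 kinds of control spot HR and NR rats at 2 Hz also differed (-0.70, SE 0.18, limma adjusted p = 0.0147 over the 16 kinds).

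In the fit set beforehand, no spot passed in the other responder comparisons, but some passed under other settings. By limma, 0 of 11207 spots differed at 100 Hz at 1 h, with 749 at an unadjusted p under 0.05, and 0 in the mean of both frequencies, with 1012. At 24 h, 0 of 10886 spots differed at 2 Hz (1045 at an unadjusted p under 0.05), at 100 Hz (478) and in the mean of both frequencies (600). The 2 Hz comparison at 1 h had 1194 such spots, where 560 would be expected by chance at 1 h and 544 at 24 h. The interaction of response with frequency gave 0 spots at 1 h (1002 at an unadjusted p under 0.05) and 0 at 24 h (808). With slide run as a block at 1 h, 17 spots passed at 100 Hz, 1 in the mean of both frequencies and 7 in the interaction. With image folder as a block at 24 h, 5 passed at 2 Hz, 41 at 100 Hz, 20 in the mean and 10 in the interaction. Array weights gave 43 spots in the mean and 143 in the interaction at 1 h, and 1 in the interaction at 24 h. A single fit of all arrays gave 3 at 100 Hz, 3 in the mean and 16 in the interaction at 1 h, and 1 in the interaction at 24 h. A replicate block gave 34 in the interaction at 1 h. The HR minus NR differences varied with position on the slide: the 48 blocks of spots held 17.6% of their variance over spots at 2 Hz and 21.3% at 100 Hz at 24 h, and 5.01% and 4.43% at 1 h.

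For most spots a difference of 2-fold between HR and NR rats lay outside the interval. The 95% interval of the difference stayed within a log2 value of 1 either way for 97.1% of spots at 2 Hz and 98.5% at 100 Hz at 1 h. At 24 h the shares were 98.8% and 99.6%. Slide run was left out of these fits. At 24 h each run held 1 group, so there the intervals cover responder and run differences together. Simulated data had the spread of these spots but noise independent between spots and arrays, so the shares called on real arrays may differ. In the simulated data, 59.7% of spots changed by 0.5 were called at 2 Hz at 1 h and 8.96% of those changed by 0.3. In the mean of both frequencies 55.2% of spots changed by 0.3 were called at 1 h and 38.8% at 24 h. The 2 Hz comparison at 1 h depended on 1 rat: without replicate 1 of the NR group it gave 210 spots, the mean of both frequencies 16 and the interaction 132. Within single slide runs, HR and NR rats differed at 0 spots at 2 Hz (155 at an unadjusted p under 0.05) and at 128 spots at 100 Hz, the latter from 3 HR and 2 NR rats. Single image folders at 24 h held 1 HR rat beside 5 NR rats at either frequency, too few HR rats for a count.

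The comparison of frequencies gave far more spots. At 1 h, 1178 spots were higher and 651 lower after 100 Hz than after 2 Hz, together 16.3% of 11207. Most differences were small: the median size among these spots was 0.29 on the log2 scale, and 14 exceeded 1, all of them higher at 100 Hz. Of the 1829 spots, 1316 were above background in both channels on every array of that time point. Of the 16 kinds of control spot, 9 also passed between frequencies at 1 h (differences from -0.20 to 0.43), among them 2 of the 3 kinds at background level.

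The largest rises among those bright spots were at Sr01Sc03R02C08 and Sr02Sc01R04C07. In the mean of HR and NR rats, the first was higher at 100 Hz by 1.48 (SE 0.23, adjusted p = 0.000472) and the second by 1.41 (SE 0.22, adjusted p = 0.000529). Against the control pool, Sr01Sc03R02C08 had a mean log2 ratio of 2.00 ± 0.27 (SD, n = 5) in 100 Hz HR rats and 1.45 ± 0.45 (SD, n = 5) in 100 Hz NR rats. The corresponding 2 Hz means were -0.44 ± 0.33 (SD, n = 5) and 0.92 ± 0.97 (SD, n = 4). For Sr02Sc01R04C07 the means were 1.81 ± 0.27 and 1.39 ± 0.45 at 100 Hz (SD, n = 5 each), against -0.43 ± 0.33 (SD, n = 5) and 0.80 ± 0.92 (SD, n = 4) at 2 Hz. At both spots the values of HR rats did not overlap between frequencies, while those of NR rats did. At Sr01Sc03R02C08 the NR rats ranged from -0.24 to 1.77 at 2 Hz and from 0.91 to 1.90 at 100 Hz. The response by frequency interaction was 1.92 (SE 0.45) at the first spot and 1.65 (SE 0.44) at the second. HR minus NR at 2 Hz was -1.37 (SE 0.33) and -1.22 (SE 0.32). None of these passed limma's threshold after adjustment. In the mean of both channels, Sr01Sc03R02C08 was also 2.12 times brighter on the 100 Hz slides (log2 1.09, beside the ratio difference of 1.48). A rise in Cy3 alone would raise that mean by 0.5 times the ratio difference. The brightness difference was larger than that, so a rise in Cy3 alone does not account for it. The largest falls were at Sr04Sc03R08C10 (-0.66, SE 0.19, limma adjusted p = 0.0237) and Sr07Sc04R10C13 (-0.60, SE 0.19, limma adjusted p = 0.0365). Under 32 alternatives, Sr07Sc04R10C13 lost its call with the same sign in 9 and reversed its sign in 1. On the 100 Hz slides at 1 h Sr04Sc03R08C10 was 12.9 times brighter over both channels, the control pool included. It was dim only on the 2 Hz slides at 1 h, with a mean log2 brightness of 7.50 in HR and 7.27 in NR rats. At 24 h the 2 Hz means were 11.59 and 11.57, close to those at 100 Hz at 1 h (11.34 and 11.76). Its fall therefore rests on dim spots of 1 set of slides and cannot be read as an effect of frequency.

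**Figure D1:**
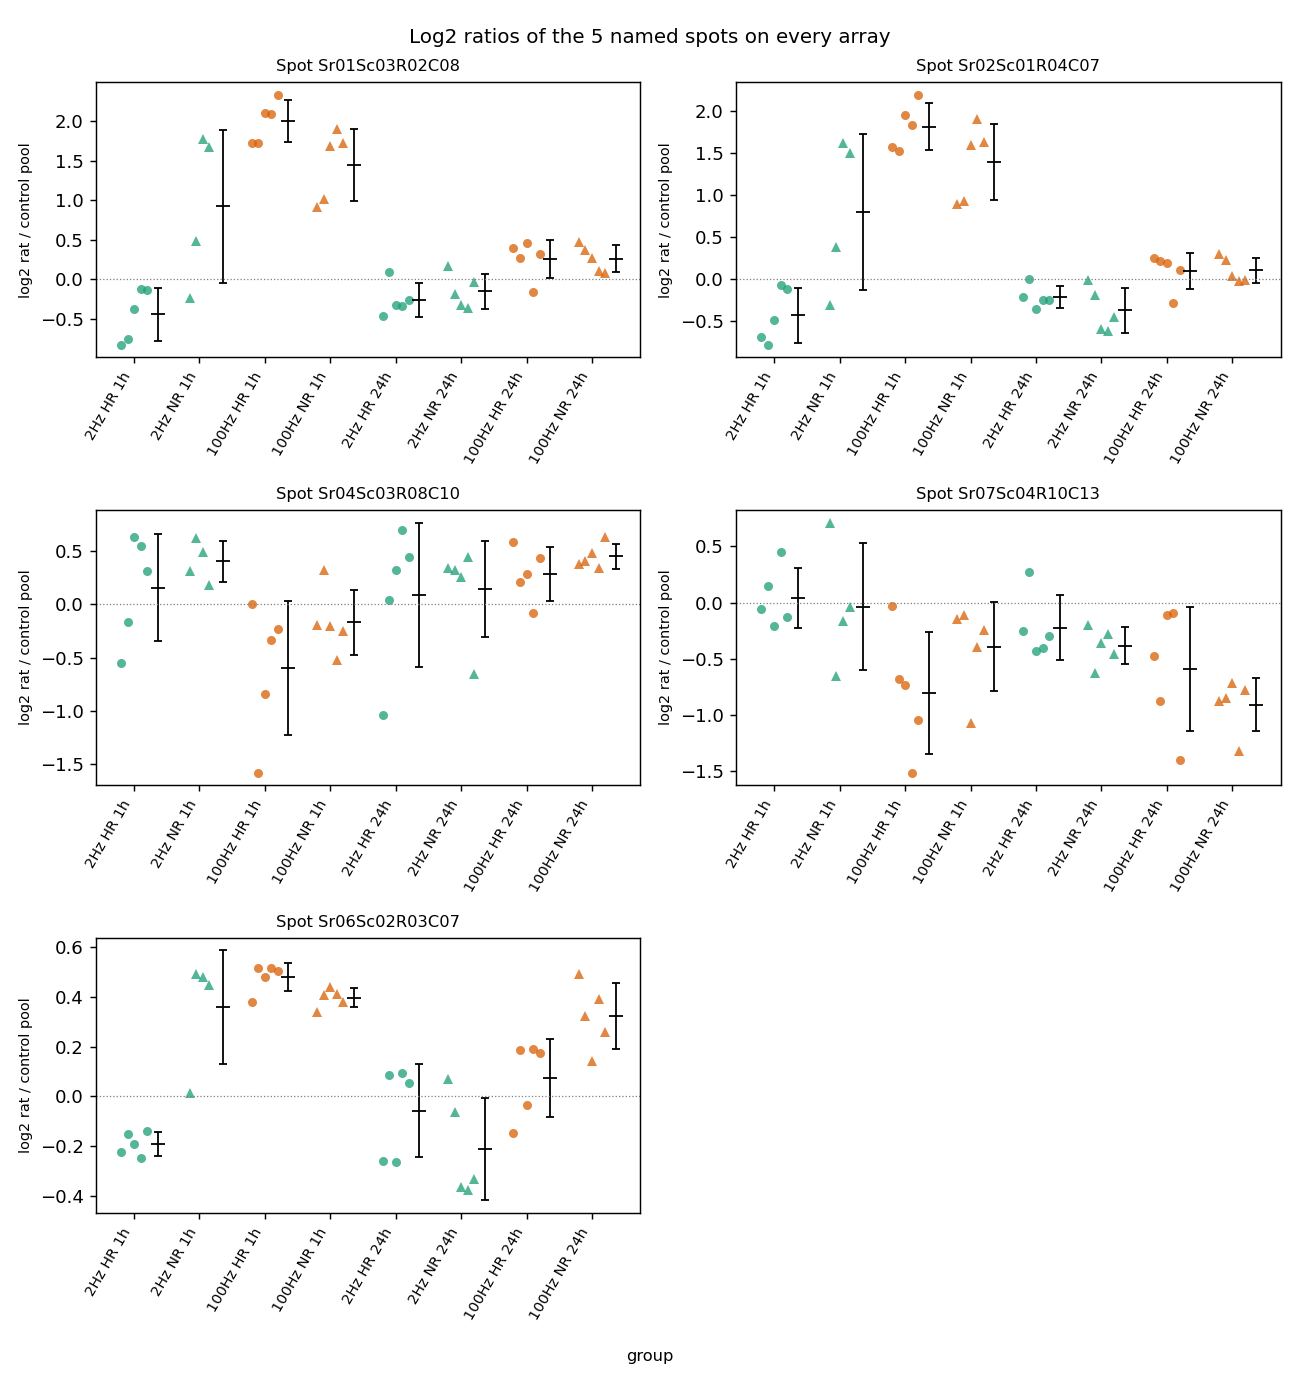
Log2 ratios of stimulated rat over control pool at the 5 named spots on every array, by group (circles HR, triangles NR, green 2 Hz, orange 100 Hz), with the group mean and SD in black. At Sr01Sc03R02C08 the 100 Hz HR rats at 1 h averaged 2.00 and the 2 Hz HR rats -0.44. The NR rats there averaged 1.45 at 100 Hz and 0.92 at 2 Hz.

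The frequency difference at 1 h could not be separated from the slides used. Slides scanned into each image folder held 1 frequency only, so at 1 h folder and frequency cannot be told apart. With slide run as a block the count fell from 1829 spots to 1, the differences of the 4 spots became 1.24, 1.21, -0.48 and 0.27, and none passed. Of the 4 runs, 1 held both frequencies (2 HR rats at 100 Hz and 3 at 2 Hz). Within it 109 spots passed, and 98.3% of the 1829 spots had the same sign, a share that includes the arrays on which they were called.

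At 24 h, 408 spots were higher and 236 lower after 100 Hz than after 2 Hz, of 10886 tested. Their median size was 0.36, and 5 exceeded 1, all higher at 100 Hz. Sr01Sc03R02C08 was again higher at 100 Hz (0.46, SE 0.09, adjusted p = 0.0142), as was Sr02Sc01R04C07 (0.39, SE 0.09, adjusted p = 0.0242). The difference at Sr04Sc03R08C10 was 0.25 (SE 0.17, adjusted p = 0.378) and at Sr07Sc04R10C13 -0.44 (SE 0.14, adjusted p = 0.0611). With each array centred on its median in place of loess, 280 spots were higher and 246 lower, and a single fit of all 39 arrays gave 1131 in total. Of the control kinds, 5 also passed at 24 h. Over the 48 blocks of the slide, the mean difference of tested spots correlated with that of control spots at 0.60. Blocks held 3.53% of the variance of this difference over spots. Each run at 24 h held a single group, so run and group cannot be told apart by a fixed block. The count ranged from 93 without replicate 3 of the 2 Hz HR group to 1293 without replicate 1 of the 2 Hz NR group. With image folder as a block it was 10. The 1 folder that held both frequencies had 4 HR rats at 100 Hz and 1 at 2 Hz, too few for a count. In that folder 91.8% of the 644 spots had the same sign, which again includes arrays on which they were called and rests on a single 2 Hz rat.

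The lists of the 2 times were also compared. Of spots tested at both times, 69 were higher at 100 Hz at both, where 43.4 would be shared by independent lists, and 18 were lower at both, where 14.0 would be. Of the spots higher at 1 h, 26 were lower at 24 h, against 25.1 for independent lists, and of those lower at 1 h, 5 were higher at 24 h, against 24.2. The sign at 24 h was the same for 49.1% of the spots higher at 1 h and 61.8% of those lower.

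Against the control pool, many spots differed in every group. At 1 h, 3032 spots were higher and 3200 lower in 2 Hz HR rats, 2794 and 3044 in 2 Hz NR, 3199 and 3339 in 100 Hz HR, and 2963 and 2965 in 100 Hz NR rats. At 24 h the counts were 944 higher and 593 lower in 2 Hz HR, 1004 and 730 in 2 Hz NR, 1257 and 1167 in 100 Hz HR, and 1732 and 1897 in 100 Hz NR rats. Leaving out 1 array moved the 24 h totals from 1537 to as few as 914 in 2 Hz HR, from 1734 to 1086 in 2 Hz NR, and from 2424 to 1506 in 100 Hz HR rats. Array weights gave 3704 in 100 Hz HR and 5620 in 100 Hz NR rats at 24 h. In all 4 groups of a time point, 1634 spots were higher and 1854 lower at 1 h, and 355 higher and 123 lower at 24 h. Independent lists of these sizes would share 57.0, 68.5, 1.60 and 0.743 spots, and simulated unchanged groups against 1 pool shared 0.25, 0.2, 0.8 and 0.35. The simulated pool, which held only the spread between rats, gave little of this excess. Other differences of the pool and those of the dyes were not simulated. The pool was a single control sample whose own spread is left out of the test, and it was always labelled with Cy5, so differences between the dyes are part of these ratios.

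**Figure D2:**
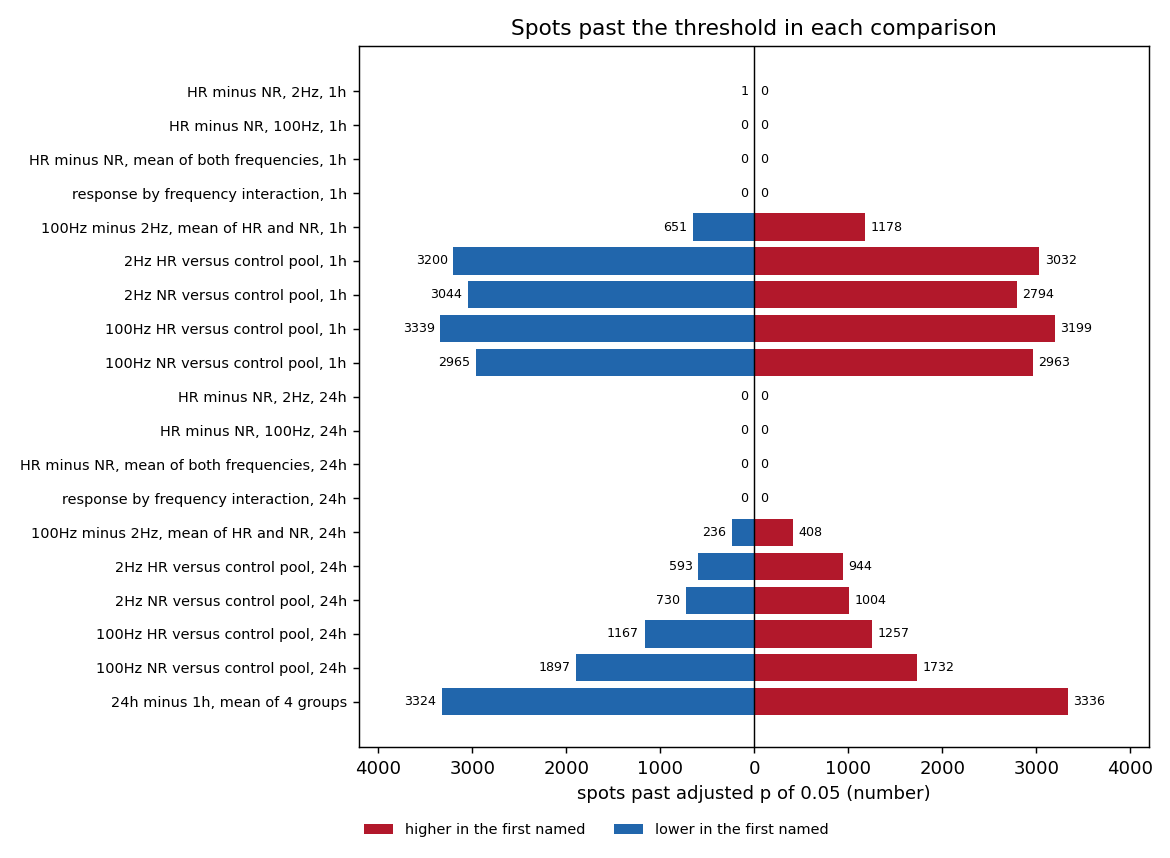
Number of spots past an adjusted p of 0.05 in each of the 19 comparisons, with higher spots to the right and lower spots to the left of 0. The responder comparisons hold 0 or 1 spot, the frequency comparisons 1829 and 644.

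The last comparison set the times against each other. Averaged over the 4 groups, 3336 of 11239 spots were higher and 3324 lower at 24 h than at 1 h. Sr01Sc03R02C08 fell by 0.96 (SE 0.12, adjusted p = 4.5e-08) and Sr02Sc01R04C07 fell by 0.99 (SE 0.12, adjusted p = 1.13e-08). No slide run or image folder held arrays of both times, so time and slide set cannot be told apart. The median Cy3 background was 190 at 1 h and 95.5 at 24 h.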

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

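Tests chosen only after the result was seen are those of slide run, printed DNA (both parts) and an effect shared by both times; the first replaced a slope over spots chosen on the same arrays and that of printed DNA over 2-fold a share of dim spots, both after their results were seen, and the bound that would argue against a shared effect was also changed then.

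Of 80 groups of values tested for a sample far from the others, 8 had one, and chance gives about 1 in 20 groups, or 4. Replicate 2 of the 2 Hz HR group at 24 h had a mean correlation of 0.127 with its own group, and replicate 4 of the 2 Hz NR group at 24 h one of 0.0509. At Sr06Sc02R03C07, replicate 1 of the 2 Hz NR group at 1 h had a log2 ratio of 0.016, with 0.45 the nearest other value, and replicate 1 of the 100 Hz HR group at 1 h had 0.38. The others were -0.28 at Sr02Sc01R04C07 in replicate 4 of 100 Hz HR at 24 h, -0.65 at Sr04Sc03R08C10 in replicate 5 of 2 Hz NR at 24 h, and, at Sr07Sc04R10C13, 0.27 in replicate 2 of 2 Hz HR and -1.32 in replicate 4 of 100 Hz NR, both at 24 h.

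Some differences changed with time, by limma over all 39 arrays. The frequency difference changed at 1218 spots and the HR minus NR difference at 2 Hz at 13; at 100 Hz it changed at 0 (767 at an unadjusted p under 0.05). The frequency difference at 24 h minus that at 1 h was -1.02 at Sr01Sc03R02C08 and at Sr02Sc01R04C07, and 0.91 at Sr04Sc03R08C10. The change of HR minus NR at Sr06Sc02R03C07 was 0.70. These 4 spots were named for their differences at 1 h, a choice that favours a smaller difference at 24 h, so they do not show a change with time. Time and slide set cannot be told apart in these values.

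Signal also appeared outside the series matrix. Of the 1012 spots there, 398 were above background in Cy3 on every array. The 1012 include 16 kinds of spot repeated at the top of all 48 blocks, treated here as control spots. Between frequencies 9 of the 16 kinds passed the threshold at 1 h (differences from -0.20 to 0.43) and 5 at 24 h; at 1 h, 2 of the 3 kinds at background level were among the 9. At 1 h, 1 of these 9 kinds also passed for HR minus NR at 2 Hz (-0.70, adjusted p = 0.0147) and for the interaction (0.91, adjusted p = 0.0240).

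The spots that differed between frequencies at 1 h were weighed first. Chance among single arrays can be excluded: 1 of 100 splits, the real one, gave 1829 spots, and the highest other gave 2. Slide run alone was tested over 1049 spots called on the 14 arrays outside the run with both frequencies. Differences within that run followed with a slope of 0.81 (0.63 to 1.00 without 1 of its 5 arrays). That argues against run alone, but only from 2 HR rats at 100 Hz and 3 at 2 Hz. The highest of the run's other splits gave 0.32. Only 10 splits exist, so the rank of the real split, 1 in 10 at best, decides nothing. Most of these spots did not differ over 2-fold in brightness, so a difference that large in printed DNA did not hold for most of them. It was seen in 2.02% of them and in 0.906% of spots not called. As it was rare in both, and the median ratio difference was only 0.29, this share does not test printed DNA as the source. Smaller differences in printed DNA stay open. Of the rest, 60.2% differed in brightness by at least 0.5 times the ratio difference (85.5% of spots not called). Ratio and brightness differences correlated at 0.38 over the 1829 spots and at 0.18 over all tested spots. These values cannot decide the question, because brightness is the mean of both channels. A change in Cy3 alone also moves it by 0.5 times the ratio difference. Image folder stays open, 9 of the 16 kinds of control spot differed as well, an effect shared with 24 h could not be decided (16 of 100 relabelings, a share of 0.16, correlated as highly), and an effect of frequency is a candidate explanation that the folders leave untested.

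The interaction of response with frequency at 24 h followed the position on the slide. Blocks held 28.9% of its variance over spots, against 0.446% when shuffled. Over the 48 blocks its mean correlated with that of the control spots (r = 0.85, rho = 0.84), which a position effect on the slides would give. The permutation p was 1e-05, the smallest 100000 permutations can give. Shuffling treats the blocks as independent, while their means changed gradually along the slide (from -0.16 to 0.17 down block column 1), so this p can be too small. HR minus NR correlated with the control spots in the same way at 100 Hz (r = 0.90, rho = 0.89) and 2 Hz (r = 0.62, rho = 0.53) at 24 h and at 2 Hz at 1 h (r = 0.78, rho = 0.78), but not at 100 Hz at 1 h (r = -0.38, rho = -0.37). For the mean of both frequencies r was 0.27 at 1 h and 0.38 at 24 h, and for the interaction at 1 h it was 0.48. The frequency difference also followed the control spots at 24 h (r = 0.60, rho = 0.65), but little at 1 h (r = 0.20, rho = 0.03). For the interaction at 24 h, loess by block left 0 spots past limma's threshold, as in the report, and 368 at an unadjusted p under 0.05, against 808, and no biological explanation was tested.

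For the other comparisons, 100 splits of the arrays were counted. Chance among single arrays can be excluded for the frequency difference at 24 h (644 spots, the highest other split 1, as many in 1 split) and for time (6660, the highest other 3, as many in 1). These splits break up the slide runs, which at 24 h held 1 group each and never both times, so they leave differences between slide sets open. With image folder as a block the 644 fell to 10. It could not be excluded for the responder comparisons, by spots at an unadjusted p under 0.05. At 1 h, as many were found in 13 splits at 2 Hz (1194, highest other 2860), 15 at 100 Hz (749, 1688), 21 for the mean (1012, 2013) and 12 for the interaction (1002, 1857). At 24 h they were found in 30 splits at 2 Hz (1045, 2696), 11 at 100 Hz (478, 1031), 24 for the mean (600, 1263) and 21 for the interaction (808, 2077). Some other splits called many spots after adjustment, up to 884 at 2 Hz at 1 h and 703 at 24 h. What the arrays of those splits have in common was not tested.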

How the results depend on the processing

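Print-tip loess, spots marked empty left out and image folder as a block were chosen only after the result was seen. Of 255 counts under alternatives other than leaving out arrays, 219 were within 1.5 times the reported count and 36 were not; the cause was not tested unless given. Aquantile leaves ratios as they are and tests nothing. Its counts for the 19 comparisons are among the 219 by construction, and it is also among the alternatives counted for the named spots. The gene-list alternatives (estimated correlation, fry, mean over probes, centring, Aquantile, no background correction, leaving out replicates) were not run, as no spot has a gene name here.

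HR minus NR at 2 Hz at 1 h gave 9 spots with plain subtraction, 3 with median centring and 0 with only the groups compared (931 at an unadjusted p under 0.05 by limma). Array weights gave 616 there, 43 for the mean of both frequencies at 1 h, 143 for the interaction at 1 h, 1 for that at 24 h, and 3704 and 5620 for 100 Hz HR and NR against the pool at 24 h. In 1 fit of all 39 arrays, the responder comparisons at 1 h gave 30 (2 Hz), 3 (100 Hz) and 3 (mean), the interaction 16 at 1 h and 1 at 24 h, and the frequency comparison at 24 h 1131. With slide run as a fixed block at 1 h they gave 0 (340 at an unadjusted p under 0.05 by limma), 17, 1, an interaction of 7 and a frequency count of 1, and Sr07Sc04R10C13 reversed to 0.27; only 1 run holds both frequencies. As a random block at 24 h, run gave 4219 (2 Hz), 1095 (100 Hz), 2587 (mean), 2806 (interaction), 5866 (frequency) and, against the pool, 6635, 6693, 5610 and 7707. Its estimated correlation was negative (-0.198), rests on the 1 group that spans 2 runs and shrinks the errors of group means by construction, so these counts show no effect. Image folder as a block at 24 h gave 5 (2 Hz), 41 (100 Hz), 20 (mean), 10 (interaction) and 10 (frequency). Within single folders at 1 h, HR minus NR gave 0 at 2 Hz and 0 at 100 Hz (1423 and 727 at an unadjusted p under 0.05 by limma). The single folders at 24 h held 1 HR rat beside 5 NR rats, too few HR rats for a count.

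Same-numbered rats did not deviate together (8 of 27 pairs at 1 h and 6 of 30 at 24 h correlated over 0.1), so the numbers do not pair them. With a replicate block, HR minus NR at 2 Hz at 1 h gave 22 spots and the interaction at 1 h 34; no other count moved by over 1.5 times.

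Leaving out each array gave these ranges: HR minus NR at 1 h 0 to 210 (2 Hz), 0 to 0 (100 Hz) and 0 to 16 (mean), interaction 0 to 132, each highest without replicate 1 of 2 Hz NR except the unchanged 100 Hz count; at 24 h 0 to 2, 0 to 0, 0 to 1 and 0 to 1. Frequency ranged over 1270 to 2007 at 1 h and 93 to 1293 at 24 h, time over 6470 to 6819. Against the pool at 1 h the ranges were 5542 to 6363, 4875 to 5896, 5536 to 6646 and 5301 to 6000. At 24 h they were 914 to 1956, 1086 to 2036, 1506 to 2894 and 2540 to 4038, lowest without replicate 3 of 2 Hz HR, 2 of 2 Hz NR, 2 of 100 Hz HR and 4 of 100 Hz NR. The call of Sr06Sc02R03C07 was lost in 12 of 33 alternatives (adjusted p 2.77e-05 to 0.641) and that of Sr07Sc04R10C13 in 10 of 32; the other 3 named spots lost theirs in 1 of 32, the slide run block. Where signal is low over background, ratios are drawn towards 0 by the offset.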

Other observations

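Tests chosen only after the result was seen are the correlations of HR minus NR differences between conditions, whose bound for arguing against a shared difference was changed after the values were seen, and the search for spots with separate levels.

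A set of 18 spots in 10 blocks rose and fell together between rats of a group, each with a correlation over 0.8 with the most variable spot of all, whose SD within groups was 1.42 against a median of 0.18. The mean log2 ratio of the set ranged from -3.02 in replicate 4 of the 2 Hz NR group at 24 h to 1.33. Its mean correlated with that from the series matrix at 0.97, so the set was not limited to the values computed here. Whether background correction or loess was its source stays open, because the steps behind the series matrix are not given. Faults of the spots or slides could not be decided: the SD of Cy3 was a median of 2.23 times that of Cy5, but 1.09 to 3.15 times over the spots. A difference between the rats is a candidate explanation that was not tested.

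At 24 h, 3 spots took 2 separate levels among the arrays, with a gap over 1.5 and at least 3 arrays on each side. The widest gap was 2.90, between 17 arrays at -3.41 to -2.31 and the others at 0.59 to 1.20. The spot with the next gap, 1.94, was high on the same arrays (replicate 5 of 2 Hz NR, replicates 1 and 5 of 100 Hz HR), so these need not be separate patterns. The last spot, with a gap of 1.52, was high on replicates 3 and 4 of 2 Hz HR and replicate 1 of 2 Hz NR. On those arrays 85.4%, 86.4% and 89.0% of spots were above background, against a median of 91.6% at 24 h. What these spots measure is not analysed here.

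If HR and NR rats differed alike in separate conditions, their differences would correlate over spots. The 6 correlations were -0.082 (2 Hz 1 h and 100 Hz 1 h), 0.10 (2 Hz 1 h and 2 Hz 24 h), 0.32 (2 Hz 1 h and 100 Hz 24 h), -0.13 (100 Hz 1 h and 2 Hz 24 h), -0.15 (100 Hz 1 h and 100 Hz 24 h) and -0.012 (2 Hz 24 h and 100 Hz 24 h). The correlation of 0.32 was reached in 4 of 100 relabelings, a share of 0.24 after adjustment over the 6. None passed, so a shared responder difference could not be decided. These are correlations over 10858 spots, which are not independent replicates.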
